A study of Arabidopsis thaliana with 6 samples.

How the data were processed

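Total RNA from 6 seed samples, 3 wild-type and 3 agl67 mutant, was hybridised to Affymetrix arrays, and the labels call the samples biological replicates. The submitters' processing notes name RMA and limma, with no version. The deposited value table holds log2 expression values from the authors, 1 per probe set and array, and the medians of the arrays are not equal. The authors' deposited comparison table holds log2 ratios of mutant over wild type, log2 values per array, and p-values with false discovery rates from limma per the file headers. It was used as an alternative source of calls, and its values per array were used only to check the direction of the ratios. The value table was analysed without further scaling. The 64 control probe sets were left out of all tests, which leaves 22746, and were used to look at RNA quality.

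Probe sets were paired with genes through the platform's table of genes (13513 with 1 gene and 502 with several) and then through the gene symbols and names in the authors' table, looked up by name in the RefSeq gene table of assembly TAIR10.1 (1206 more, and 45 more for members of the fixed gene lists). Numbers of probe sets follow the chromosomes, so a gene found through the authors' table was kept only where at least 1 of the 10 platform-named probe sets nearest in number lies on its chromosome. This check was added after results were seen and uses no expression value. It left 34 probe sets unnamed. Of probe sets with 1 platform gene 99.7% pass it, and 22.9% do on average when each is given any of these genes, so wrong pairs can remain. In all 14765 probe sets name 1 gene, 544 name several and 7437 are unnamed. Of 169 probe sets that both sources name, 154 (91.1%) were given the same gene, and of the 157 that pass the check, 153. No genome coordinates are given, since the files name no build. ABI5 and DOG1 have no probe set paired with them and are not analysed here.

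The main comparison was a linear model with genotype as the only term, fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with default settings), mutant minus wild type. P-values were adjusted by the Benjamini-Hochberg method over all 22746 probe sets, with a threshold of 0.05. P-values measure spread between these samples. AGL67 was also tested with an exact permutation test, two-sided. For gene lists, 1 probe set per gene was kept, that with the highest mean over the 6 arrays (14593 genes). Of 29 lists fixed before the data were examined, the 23 with at least 5 measured members were tested with camera at its preset correlation of 0.01, again with Benjamini-Hochberg adjustment and a threshold of 0.05. The written-out lists name 486 genes. Of these, 279 were paired with a probe set naming 1 gene and are called measured here. The others may have a probe set among those left unnamed or naming several genes. The lists of plastid-encoded and of mitochondrion-encoded genes had 0 members. Of the 23 lists, 6 passed with the preset correlation, 0 with an estimated correlation, and 5 with fry, which tests whether a list's genes move on balance in 1 direction and makes no comparison with other genes. By fry these were seed dormancy (adjusted p = 0.0489), photosynthesis (0.00568), lipid mobilisation (0.0168), antioxidants (0.00257) and rapid stress genes (0.0168).

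Named genes were chosen by a rule fixed before the data were examined. The rule takes AGL67, then the 12 largest rises and the 12 largest falls among probe sets that passed, name 1 gene and have the mutant arrays on 1 side of the wild-type arrays, then up to 4 members past the threshold from each list or, where none passed, up to 2 with the smallest p-values, and ABI3, EM1 and EM6 in any case. ABI1, RD29B, AUX1, PIF4, SDP1, CAT1, AT2G43030 and AT4G01310, which fall outside this rule, were chosen after their values were seen, as were AGP4, AGP7 and AGP21. The result of 1 list member is not reported here.

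The fit was tested on simulated data with the spread of these 6 arrays and 22746 probe sets. It recovered 10 of 50 changes of 0.5 (20%), 45 of 50 changes of 1 (90%), 50 of 50 changes of 2 and 50 of 50 changes of 3 on the log2 scale, and 7 of 162 calls (4.32%) were false. In simulated lists a shift of 0.5 in 1 list was called and 0 of the other lists were. The values were drawn independently for each probe set, and no array was made to deviate from the others. The simulation therefore does not show how often lists of correlated genes are called falsely. The estimated correlation within the seed storage list, for example, was 0.352. In the other splits of the 6 arrays into 3 and 3, which mix the genotypes, camera at its preset correlation called from 0 to 5 lists, against 6 in the real split. In these other splits 0 probe sets passed, so list calls at this setting can arise where the groups mix the genotypes.

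Alternatives were a block for the replicate number, leaving out each array, an intensity trend or robust estimation in eBayes, array weights, renewed quantile normalisation, median centring, leaving out the dimmest 40% of probe sets, a minimum log2 change of 0.5 (treat), a threshold of 0.10, 1 probe set per gene, an unmoderated statistic, and the authors' deposited table. For lists, an estimated correlation, fry, all probe sets of each gene and leaving out the neighbours of AGL67 were added. After seeing the data, cyclic loess and quantile normalisation without the third wild-type array were added. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3.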

Results

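Gene expression was measured on 6 Affymetrix arrays hybridised with RNA from seeds of Arabidopsis thaliana. Of these, 3 came from wild-type Col-0 seeds and 3 from seeds of an agl67 mutant. AGL67 (AT1G77950) encodes a MADS-box transcription factor. All seeds had imbibed water for 3 days at 4 °C in darkness, a treatment used to break dormancy, and were then kept for 3 hours at 22 °C in light with 5 µM abscisic acid (ABA), the hormone that holds back germination. Each array gave log2 expression values for 22746 probe sets other than controls, and 14765 of these name 1 gene. Genes called measured below are those paired with such a probe set, and listed genes without one may still be on the array. The number of arrays limits the precision. Array medians lay between 3.97 and 4.00 on 5 arrays and at 3.80 on the third wild-type array. Across all probe sets, which are not independent replicates, the third wild-type array correlated at r = 0.980 and 0.983 with the other wild-type arrays. Those 2 correlated at 0.994, and the mutant arrays with each other at 0.996 to 0.997. The first principal component (60.2% of the variance) put the third wild-type array at 58.1 and the others at -27.7 to 6.36. On the second (21.0%) the mutant arrays lay at -13.5 to -9.06, the first and second wild-type arrays at 24.1 and 23.0, and the third wild-type array at -13.8. For the actin control transcript, 1 pair of probe sets read higher at the 3′ end than at the 5′ end by 4.18 on that array and by 3.18 to 3.59 on the others, and the other pair by 0.80 against 0.47 to 0.65. The GAPDH gaps were 1.07 on that array against 0.95 to 1.29, and -0.31 against -0.21 to -0.01, while both ubiquitin gaps, 1.10 and -0.60, lay within the range of the others. The first GAPDH gap parted the genotypes, with means of 1.15 in wild type and 1.02 in the mutant (exact permutation test, two-sided, p = 0.1). So did 8 of 18 probe sets of the hybridisation spike-ins, all higher on the mutant arrays, and 8 of 27 for Bacillus subtilis transcripts, 1 higher and 7 lower, where chance gives 10%. Of the spike-ins bioB, bioC, bioD and cre, only bioB and bioC held such probe sets, so the 8 are not independent.

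The comparison asks which transcripts differ in seeds of the agl67 mutant after cold imbibition and 3 hours of ABA. Mutant seeds held far less AGL67 transcript, higher levels of transcripts for cell wall enzymes (XTH24, TCH4, XTH19), the calmodulin-like protein TCH2, the iron superoxide dismutase FSD1 and the fatty acid desaturases FAD3 and FAD2, and lower levels of the seed storage protein transcripts SESA4 and CRU2. The bZIP gene EEL and the ABA-insensitivity gene ABI4, regulators of ABA responses in seeds, rose. GA2OX2, which encodes a gibberellin-inactivating enzyme, fell. In the 6 fits that leave out 1 array, EEL and CRU2 passed in 1, ABI4 in 2, SESA4, TCH4 and FAD2 in 3, XTH19 in 4, TCH2 in 5 and the other genes named here in all 6. Across the array 615 probe sets changed at an adjusted p under 0.05 in limma, 438 of them higher and 177 lower in the mutant. Of the 615, 340 name 1 gene, 12 name several and 263 are unnamed.

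AGL67 had a log2 level of 8.61 ± 0.31 (SD, n = 3) in wild-type seeds and 4.03 ± 0.33 (SD, n = 3) in mutant seeds. It fell by 4.57 (SE 0.21) on the log2 scale, 23.8-fold lower, with a limma adjusted p of 0.000887, and had the smallest p-value of all probe sets tested. The exact permutation test, two-sided, gave p = 0.1, the smallest value that 3 arrays against 3 allow. The mutant mean stood at the 50.6th percentile of all probe sets and the wild-type mean at the 91.9th. Whether the mutant level lies above background was not tested, so 23.8-fold is a ratio of readings.

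**Figure D1:**
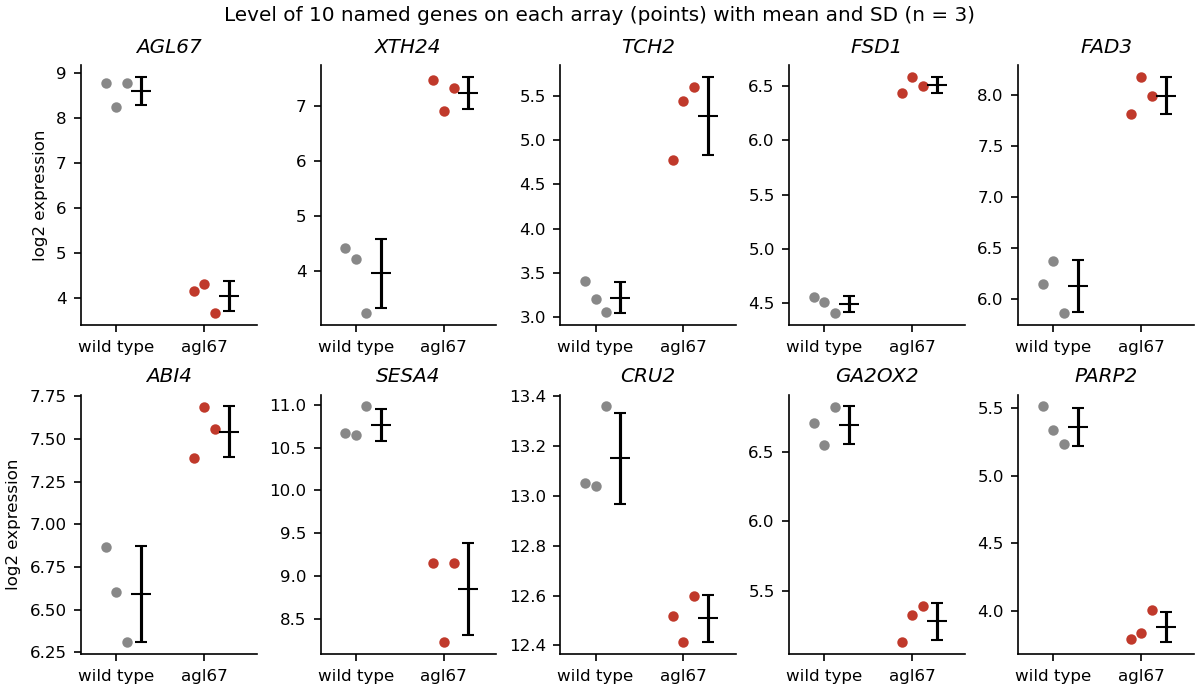
Log2 expression of 10 named genes on each of the 3 wild-type arrays (grey points) and the 3 agl67 mutant arrays (red points), with the mean and SD beside them; each panel has its own vertical axis, which does not start at 0. AGL67 lies at 8.61 in wild type and 4.03 in the mutant, and for each gene the mutant arrays lie on 1 side of the wild-type arrays.

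Among probe sets naming 1 gene, large rises were those of XTH24 and AT1G71250. XTH24, which encodes a xyloglucan endotransglucosylase of the cell wall, rose from 3.97 ± 0.63 to 7.23 ± 0.29 (SD, n = 3), a log2 change of 3.26 (SE 0.31, adjusted p = 0.00432). AT1G71250, a gene for a GDSL-motif lipase, rose by 3.22, and in the authors' deposited table the ratios of these genes were 2.84 and 3.20. Another gene for such a lipase, AT5G14450, rose by 2.19. The flavin-containing monooxygenase gene FMO (AT1G12200) rose by 2.14, the harpin-induced family gene AT2G27080 by 2.11 and the arabinogalactan protein gene AGP12 by 2.05. EXO, a gene linked to brassinosteroid-dependent growth, and TCH2, a touch-induced gene, each rose by 2.05. FSD1 rose from 4.49 ± 0.07 to 6.50 ± 0.07 (SD, n = 3), a log2 change of 2.01. The remaining members of the 12 largest rises were the MATE transporter gene AT5G52450 with 1.98, the FK506-binding protein gene AT5G48570 with 1.97 and the aspartyl protease gene AT4G16563 with 1.96. FMO, AGP12 and AT5G52450 did not pass without any 1 of the mutant arrays (log2 changes from 1.93 to 2.18), AT5G48570 without the second mutant array (1.83) or the third mutant array (1.86) and TCH2 without the second mutant array (1.96). AT4G16563 passed only without the first wild-type array (2.19) or the third wild-type array (1.65).

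Among the falls other than AGL67, of probe sets naming 1 gene, SESA4, a 2S albumin gene, fell from 10.76 ± 0.19 to 8.85 ± 0.54 (SD, n = 3), a log2 change of -1.91 (SE 0.26, adjusted p = 0.0130). SESA4 did not pass without the second wild-type array (-1.98, adjusted p = 0.0547), the first mutant array (-2.07, 0.0516) or the third mutant array (-2.07, 0.0570). AT3G04010, of glycosyl hydrolase family 17, fell by 1.83, the chitinase gene AT2G43590 by 1.78 and AT1G27030, which the files call only an expressed protein, by 1.70. The CTP synthase gene AT4G20320 fell by 1.63. AT5G06330, another harpin-responsive family gene, fell by 1.58. PARP2, which encodes a poly(ADP-ribose) polymerase active in the response to DNA damage, fell by 1.48, and GA2OX2 fell by 1.41. ADC2, an arginine decarboxylase gene of polyamine synthesis, fell by 1.38. The MATE transporter gene AT1G61890 and the ubiquitin-conjugating enzyme gene UBC3 each fell by 1.37, and the DnaJ-domain gene AT1G56300 fell by 1.34. AT4G20320 did not pass without the second wild-type array (-1.64) or the third mutant array (-1.74), ADC2 without the second mutant array (-1.32) or the third mutant array (-1.28), and AT1G56300 without the second wild-type (-1.27), first mutant (-1.30) or the third mutant array (-1.26). AT1G61890 passed only without the first (-1.17) or the third (-1.47) wild-type array.

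Of the 11 measured seed storage protein genes, 3 fell, 1 rose and 7 did not pass, with the same counts adjusted over the list alone. Besides SESA4, the cupin gene AT1G03890 fell by 0.73 and the cruciferin gene CRU2 by 0.64, while the vicilin-like gene AT4G36700 rose by 0.51. Of the 6 fits that leave out 1 array, CRU2 (-0.54) and AT4G36700 (0.49) passed only in that without the third wild-type array, and AT1G03890 in that (-0.65) and in that without the first (-0.82). The list stood lower than other genes in camera (median log2 change -0.41, adjusted p = 0.000388), and did not pass with an estimated correlation (adjusted p = 0.606) or with fry (0.0908). The median was -0.21 without the third wild-type array and -0.23 without the second mutant array. Late embryogenesis abundant (LEA) proteins protect the drying seed; none of their 25 measured genes passed, over all probe sets or adjusted over the list alone, and ECP63 with 0.65 and AT3G53040 with 0.41 had the smallest p-values. The LEA list did not pass in camera (adjusted p = 0.449, and 0.929 with an estimated correlation). Its direction in camera turned with the array left out, up without the third wild-type array (adjusted p = 0.00301) and down without the first (0.850) or the second (0.982). Without the third wild-type array ECP63 and AT3G53040 passed, with 0.79 and 0.48. EM1 and EM6, LEA genes activated by ABA, differed by 0.13 and 0.02, and by 0.05 and 0.00 without the third mutant array, and neither passed. Among 9 genes for oil bodies and oil synthesis, 2 rose, 1 fell and 6 did not pass, with the same counts adjusted over the list alone. The risers were FAD3 with 1.86 and FAD2 with 1.42, desaturases of the endoplasmic reticulum, and the oil body caleosin gene CLO1 fell by 0.60 (camera adjusted p = 0.449). FAD2 did not pass without any 1 of the mutant arrays (1.39 to 1.46), and CLO1 passed only without the first wild-type array (-0.60) or the third wild-type array (-0.59).

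In the core of ABA signalling, 9 of 34 listed genes were measured, of which 2 rose and 7 did not pass. EEL rose by 1.00 and ABI4 by 0.95. With 1 array left out, EEL passed only without the third wild-type array (0.99), and ABI4 only without the first (1.09) or the third (0.81). In the authors' deposited table the false discovery rate was 0.0564 for EEL and 0.0330 for ABI4. Adjusted over the list alone, 2 were higher and 1 lower, the latter being the phosphatase gene ABI1 with -0.70, which did not pass over all probe sets (adjusted p = 0.0607) and passed there without the third wild-type array, with -0.80. ABI3, a master regulator of seed maturation, had a log2 change of -0.36 and did not pass. None of 16 ABA-responsive genes passed. Of these, 5 had a log2 change above 0, and the list median was -0.12. Adjusted over the list alone 3 were higher, HVA22A with 1.20, RD29B with 0.50 and ALDH7B4 with 0.40. HVA22A passed over all probe sets without the first wild-type array, with 1.47, and without the third, with 0.90, and ALDH7B4 without the third, with 0.43. Of 12 seed dormancy and maturation regulators, ABI4 alone rose and 11 did not pass, with the same count adjusted over the list alone. In the gibberellin list GA2OX2 fell, over all probe sets and adjusted over the list alone, and the other 17 measured genes did not pass. In none of these 4 lists did camera pass the threshold (adjusted p = 0.992 for signalling, 0.746 for responsive genes, 0.600 for dormancy and 0.998 for gibberellin). Of 14 listed genes of ABA synthesis and catabolism 3 were measured, too few for a list test, and none passed, with ABA1 at -0.07 and ABA3 at -0.11. Their signs turned with 1 array left out, ABA1 to 0.02 without the third wild-type array and ABA3 to 0.04 without the first mutant array.

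Camera called 3 lists of growth and greening higher in the mutant. In splits of the arrays that mix the genotypes it called up to 5 lists, so such a call alone does not single out the genotype. Cell wall loosening genes had a median log2 change of 0.24 (camera adjusted p = 0.00923, and adjusted p = 0.606 with an estimated correlation). This call was also lost with fry (adjusted p = 0.0545), when the dimmest 40% of probe sets were left out (0.165) and without the first wild-type array (0.125). XTH19 rose by 1.11 and the other 14 measured genes did not pass, and 5 were higher adjusted over the list alone. XTH19 did not pass without the second mutant array (1.08) or the third mutant array (1.07). The list median was 0.16 without the third mutant array. Photosynthesis genes had a median of 0.16 (camera adjusted p = 0.00726, and adjusted p = 0.325 with an estimated correlation). RCA, which encodes Rubisco activase, rose by 1.29, the other 13 did not pass, and 5 were higher adjusted over the list alone. RCA did not pass without any 1 of the mutant arrays (1.23 to 1.36). Without the first wild-type array camera gave this list an adjusted p of 0.0663. Of 218 genes taken by title as those of cytosolic ribosomal proteins, 6 rose and 212 did not pass, with the same counts adjusted over the list alone. Examples were AT5G60670 (L12) with 0.89, AT2G40010 (P0) with 0.83, AT3G10610 (S17) with 0.64 and AT3G16780 (L19) with 0.62. Without the third wild-type array these 4 passed, with 0.75, 0.72, 0.54 and 0.61, and of the other fits that leave out 1 array only that without the first wild-type array kept a call, for AT2G40010 (0.99). The titles of the other 2 risen genes, AT2G43030 and AT4G01310, do not say that their proteins are cytosolic. The ribosomal median was 0.13 (camera adjusted p = 0.000388, and adjusted p = 0.651 with an estimated correlation and 0.175 with fry), and 0.08 without the third wild-type array.

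Of 17 light and photomorphogenesis genes, 3 fell and 14 did not pass. SPA1, a repressor of light signalling, fell by 0.74, the early light-induced gene ELIP1 by 0.69 and the photoreceptor gene PHYB by 0.65. With 1 array left out, SPA1 passed only without the third wild-type array (-0.85), PHYB without the first (-0.64) or the third (-0.68), and ELIP1 in the 3 fits without a wild-type array (-0.73 to -0.66). SPA1 had a false discovery rate of 0.0797 in the authors' deposited table. Adjusted over the list alone, the same 3 were lower and 1, PIF4 with 0.63, was higher (camera adjusted p = 0.254). In the list of lipid mobilisation and the glyoxylate cycle, PXA1, which encodes the peroxisomal importer of fatty acids, fell by 0.62, 9 genes did not pass, and 2, PXA1 and the lipase gene SDP1 with -0.55, were lower adjusted over the list alone (camera adjusted p = 0.285). SDP1 passed over all probe sets without the third wild-type array, with -0.53, and PXA1 passed in that fit alone of the 6, with -0.67.

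Camera also called 2 lists of stress and redox genes higher. Among 11 rapid stress, touch and cold genes, TCH2 and TCH4 rose, by 2.05 and 1.05, and 9 did not pass, with the same counts adjusted over the list alone. TCH4 encodes another xyloglucan enzyme of the cell wall. TCH2 did not pass without the second mutant array (1.96), nor TCH4 without any 1 of the mutant arrays (0.99 to 1.11). The list median was 0.26 (camera adjusted p = 0.00424, and adjusted p = 0.325 with an estimated correlation), and 0.17 without the third wild-type array. Of 13 antioxidant genes, FSD1 and the ascorbate peroxidase gene APX1, with 0.59, rose and 11 did not pass. APX1 passed only without the third wild-type array among the fits that leave out 1 array (0.50), and its false discovery rate in the authors' deposited table was 0.0742. Adjusted over the list alone, these 2 were higher and 1, the catalase gene CAT1 with -0.44, was lower. The antioxidant median was 0.19 (camera adjusted p = 0.0209, and adjusted p = 0.325 with an estimated correlation). Camera did not pass for antioxidants without the first wild-type array (adjusted p = 0.113), the second wild-type array (0.135), the first mutant array (0.0615) or the dimmest 40% of probe sets (0.153). None of 11 heat shock genes passed, over all probe sets or adjusted over the list alone, with HSP15.7 at 0.81 and HSP23.5 at 0.81 (camera adjusted p = 0.998), and HSP15.7 passed without the first wild-type array, with 1.12. RS6, a raffinose synthase family gene and 1 of 2 measured genes for raffinose sugars and compatible solutes, rose by 1.63 and did not pass without any 1 of the mutant arrays (1.55 to 1.71), and that list was too small to test.

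**Figure D2:**
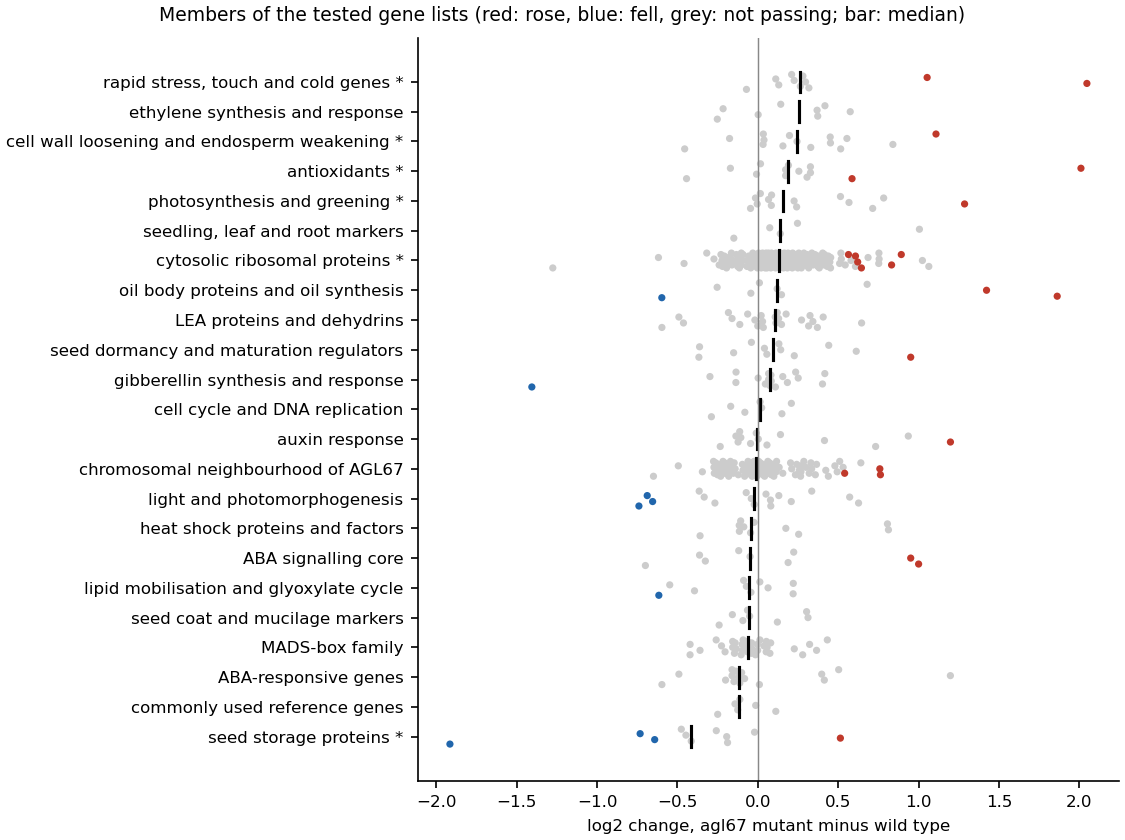
Log2 change (mutant minus wild type) of each measured member of the 23 tested gene lists; black bars are list medians, coloured points passed the test over all probe sets, and asterisks mark the 6 lists past the camera threshold with its preset correlation. Seed storage proteins have the lowest median, -0.41, and rapid stress, touch and cold genes the highest, 0.26.

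Among hormone lists, the auxin-conjugating gene GH3.5 rose by 1.20 and the other 13 auxin genes did not pass, with GH3.5 and the auxin importer gene AUX1, at 0.94, among those higher adjusted over the list alone (camera adjusted p = 0.746). None of 8 ethylene genes passed, with the receptor gene ERS1 at 0.57 and ACO4 at 0.37, and 1, ERS1, was higher adjusted over the list alone (camera adjusted p = 0.449). Without the third wild-type array AUX1 passed with 0.73 and ERS1 with 0.48. GH3.5 did not pass without any 1 of the mutant arrays (1.14 to 1.26). None of 37 other MADS-box genes passed, over all probe sets or adjusted over the list alone, with AGL15 at -0.42 and AGL18 at 0.28, and at -0.27 and 0.15 without the third wild-type array (camera adjusted p = 0.260). No gene passed, by either adjustment, among 7 cell cycle genes (CYCB1.1 at -0.29, MCM7 at 0.21), 8 seed coat markers (SBT1.7 at 0.30, GL2 at -0.24) and 6 reference genes (GAPC1 at -0.25, SAND at -0.14). Their camera adjusted p-values were 0.746, 0.870 and 0.285. GL2 was at -0.16 without the second wild-type array and SAND at -0.08 without the first. None of 5 seedling, leaf and root markers passed, with NIA2 at 1.01 and SHR at 0.25 (0.10 without the second wild-type array), and 1 was higher adjusted over the list alone (camera adjusted p = 0.449). No gene passed among the 3 jasmonate and 4 circadian genes measured (AOS at 0.20, LOX2 at -0.06, PRR5 at 0.32, GI at -0.26), lists too small to test. PRR5 turned to -0.03 without the third wild-type array and LOX2 to 0.01 without the second, and AOS was at 0.09 without the first mutant array. Of 108 genes near AGL67 on its chromosome, AT1G77060, AT1G77480 and AT1G78150 rose, by 0.76, 0.76 and 0.54, and 105 did not pass (camera adjusted p = 0.746). Without the third wild-type array they passed, with 0.78, 0.66 and 0.53, and of the other fits that leave out 1 array only that without the first wild-type array kept a call, for AT1G77060 (0.68). Adjusted over that list alone, 3 were higher and 1 lower. The list median and mean differed in sign for ABA signalling, ABA-responsive, heat shock, cell cycle, auxin, seed coat and neighbouring genes and for the jasmonate genes. The medians of the cell cycle list, 0.01, and the auxin list, -0.00333, lay near 0, and their signs are not read here. The cell cycle median was -0.05 with the arrays median-centred, which moves all genes alike, and -0.05 with quantile normalisation that also leaves out the third wild-type array. The auxin median was 0.01 after renewed quantile normalisation and 0.00397 where that array was left out as well.

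All 615 changed probe sets had the 3 mutant arrays on 1 side of the 3 wild-type arrays. Their largest unadjusted p in limma was 0.00135, which leaves little room for overlap, so this separation adds no support to the calls. Of all probe sets tested 24.0% were separated in this way, where chance gives 10%. A change of at least 2-fold was seen for 199 risen and 39 fallen probe sets. The count was 1530 without the third wild-type array, 227 without the second wild-type array, 117 without the first mutant array, 93 without the second mutant array and 86 without the third mutant array. Of 49 named genes past the threshold besides AGL67, 49, 27, 19, 17 and 15 passed in those fits, and 38 passed without the first wild-type array. All 49 kept their direction in each. Leaving out 1 array could not turn it, since the arrays of the genotypes lie apart for each of these genes. The genes past the threshold in all 6 such fits numbered 14, among them XTH24, FSD1, FAD3, EXO, GA2OX2, PARP2 and UBC3. The share of changed probe sets that were higher was 71.2%. It was 57.3% (877 higher, 653 lower) without the third wild-type array, 56.9% (593 higher, 449 lower) when the arrays were quantile-normalised again and 59.1% (691 higher, 479 lower) after cyclic loess. A false discovery rate under 0.05 was given to 512 probe sets in the authors' deposited table, and 464 of these were among the 615, all in the same direction. No seeds without ABA were compared here, so the response to ABA itself was not measured.

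**Figure D3:**
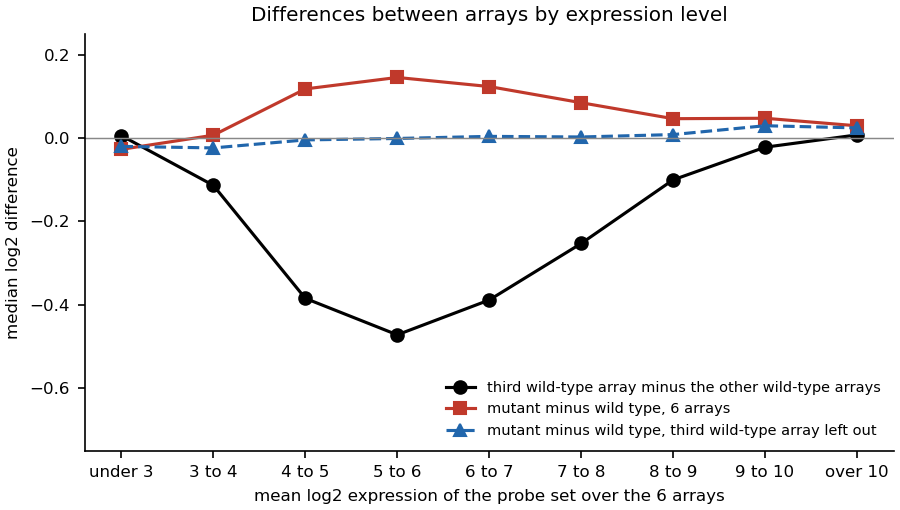
Median log2 difference against the mean log2 expression of the probe set over the 6 arrays, in steps of 1; black circles give the third wild-type array minus the mean of the other wild-type arrays, red squares the mutant minus wild type with all 6 arrays, and blue triangles the same without the third wild-type array. The the third wild-type array lies lowest, at -0.47, for probe sets between 5 and 6, where the difference between mutant and wild type is 0.15 with that array and 0.00 without it.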

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

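AGL67 stayed past the threshold in the 17 alternatives with values for named genes, with adjusted p of 0.0153 or less. Its log2 change was -5.09 in the authors' deposited table and -4.75 to -4.39 in the refits. It did not pass without moderation (adjusted p = 0.0566). Of the 49 other named genes past the threshold none turned its direction in those 17, and 14 passed in each of the 17, while 0 passed without moderation. The kept direction is no support in most of these settings. Leaving out 1 array cannot turn it where the arrays of the genotypes lie apart, as they do for these genes. Settings that change only the test leave the log2 change as it is. The counts moved more. Leaving out 1 array gave 86 to 1530 changed probe sets, 68 to 877 higher and 18 to 653 lower. The highest counts came without the third wild-type array and the lowest without the third mutant array; without the second wild-type array 227 changed, and without the first and second mutant arrays 117 and 93. Array weights, which put that of the third wild-type array at 0.209, gave 1490 changed (956 higher, 534 lower). Renewed quantile normalisation gave 1042 (593 and 449), and median centring 900 (560 and 340). A minimum log2 change of 0.5 gave 55 (42 and 13), and a threshold of 0.10 gave 1150 (814 and 336). Keeping 1 probe set per gene gave 295 (205 and 90), with fewer probe sets tested. Without moderation 1 probe set passed (1 and 0; 3091 at an unadjusted p under 0.05). Added after seeing the data, quantile normalisation without the third wild-type array gave 1602 (864 and 738), and cyclic loess 1170 (691 and 479). Changed, higher and lower counts all stayed within 1.5 times of the reported ones without the first wild-type array (613 changed) and with the intensity trend (704). The same held for robust estimation (594), the authors' deposited table (512) and leaving out the dimmest 40% of probe sets (716). Median centring (900) and the replicate block (443) kept the changed and higher counts within 1.5 times, but not the lower count. Signal over background was not measured. Except for the smaller set of genes, the causes of these shifts were not tested. Gene lists past the threshold numbered 6. They numbered 3 without the first wild-type array, 7 without the third, 0 with an estimated correlation, and 4 to 7 in the other alternatives.

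With the replicate number as a block, 443 probe sets changed, 333 higher and 110 lower, and 6 gene lists passed. Deviations from the group means correlated at -0.158, 0.145 and 0.217 between arrays of the same number in the 2 genotypes. Between arrays of different numbers they correlated at -0.335 to 0.337. With 3 arrays per group, and the third wild-type array far from the others, these values cannot tell whether the numbers pair the arrays.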

Other observations

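The new tests in this part were chosen after the results were seen, except the count of gene lists in other splits of the arrays. Results repeated here from camera, fry, the fits that leave out an array and renewed quantile normalisation of all arrays come from planned settings. Their use to weigh explanations was chosen after the results were seen.

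Of 342 families of at least 10 probe sets, taken from the gene titles in the authors' table, 1 held more risen probe sets than chance gives and 0 held more fallen ones, each direction tested with a one-sided hypergeometric test and adjusted over all 684 tests. This was the endo-xyloglucan transferase family, whose enzymes cut and rejoin the xyloglucan of growing cell walls. Of its 33 probe sets 6 rose, 0 fell and 27 did not pass (adjusted p = 0.0240). XTH24, TCH4 and XTH19 are among the risen members, and TCH4 did not pass without any 1 of the mutant arrays, nor XTH19 without the second or the third mutant array. The call rests on XTH24, because the same family under its other titles, xyloglucan endotransglycosylase and xyloglucan:xyloglucosyl transferase, lacks that probe set, had 5 risen of 32 and did not pass (adjusted p = 0.0774 for each). Arabinogalactan proteins, glycoproteins of the cell surface, had 4 risen of 23 probe sets, AGP12, AGP4, AGP7 and AGP21, and did not pass (adjusted p = 0.119). Aspartyl proteases had 5 risen of 49 and did not pass either (adjusted p = 0.208).

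Rises outnumbered falls, 438 to 177. The third wild-type array read lower than the other wild-type arrays for probe sets of middle level, by -0.47 between 5 and 6 on the log2 scale, and whether this accounts for the surplus stays open. The share of changed probe sets that were higher was 57.3% without it and 71.2% with it. More probe sets passed in both directions without it, 877 and 653, and the surplus in number was 224 of 1530 against 261 of 615. Renewed quantile normalisation gave 593 higher and 449 lower (56.9% higher). With that array left out as well, a setting added after seeing the data, it gave 864 and 738 (53.9%). Of the 615, 100% also passed without that array in the same direction, so these calls can be made without it. How far that array shaped which probe sets were called cannot be settled in this way. It had the lowest array weight, 0.209, and the count rose to 1530 without it, so passing was easier in that fit. Too few other splits of the arrays exist for a share under 0.05: the real split gave 615 changed, 438 higher and 177 lower, 1 of 10 splits reached each of these counts, and the highest of the others was 0 for each (limma; up to 1061 probe sets at an unadjusted p under 0.05, against 3730). A technical difference between the genotypes also stays open. The mutant arrays lay above the wild-type arrays for 8 of 18 probe sets of the hybridisation spike-ins (median log2 difference of the 18, 0.20). Chance gives 10% on 1 side or the other, but the 8 all belong to bioB and bioC and are not independent. For all 18 the mutant mean was the higher one, by 0.02 to 0.46. Bacillus subtilis transcripts had 1 above and 7 below of 27 probe sets (median -0.18). Their median level was 2.95 against 8.43 for the spike-ins, so they say little about a shift of brighter signals. Plant transcripts, at a median level of 10.39, had 1 above and 3 below of 19 (median -0.00264) and showed no common shift. A difference between the genotypes in handling or harvest of the seeds was not tested.

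The seed storage protein list was lower in the mutant, with a median log2 change of -0.41, in camera at its preset correlation (adjusted p = 0.000388, and 0.0000107 to 0.606 over the alternatives). It did not pass with an estimated correlation (0.606) or fry (0.0908). A lower reading of bright probe sets on the mutant arrays is argued against by 161 genes matched in mean level, whose median was 0.0572 with a 25th percentile of -0.06. The median was -0.21 without the third wild-type array and -0.23 without the second mutant array, and stayed below 0 in each fit that leaves out 1 array. Without the third wild-type array camera at its preset correlation gave adjusted p = 0.0145. The estimated correlation of the list was 0.352 against the preset 0.01, so this p-value cannot settle how far that array is the source. A fall of the seed maturation transcripts as a whole, a biological hypothesis, would take the LEA genes down too. Their median was 0.11 with a 25th percentile of -0.06, and medians were 0.01 to 0.14 in the fits that leave out 1 array. These values argue against a fall that the LEA transcripts shared in these ABA-treated seeds. ABA activates LEA genes such as EM1 and EM6, so the LEA genes cannot show whether maturation transcripts would have fallen without ABA. A narrower effect of AGL67 on storage protein genes stays open and was not tested, and the real split gave 6 called lists where the highest of the others gave 5, with 1 of 10 splits reaching 6, too few splits for a share under 0.05.

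Changes linked to the mutated locus, such as an effect of an insertion on nearby genes or a stretch of foreign chromosome, could raise the share of changed genes near AGL67. That share was 2.78% (3 of 108 genes) against 2.32% of 14484 other genes (odds ratio 1.20, 95% interval 0.243 to 3.64, Fisher's exact test, two-sided, p = 0.741). The interval is too wide to tell linked changes apart from their absence, and 336 changed genes lie elsewhere.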
